A study of Mus musculus with 4 samples.

How the data were processed

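Fibroblasts were isolated from 4T1 tumours of Balb/c mice by depletion, per the labels' protocols: cells carrying CD45, CD31, CD326 or human CD2 were bound to magnetic beads and removed over a column, the unbound mesenchymal fraction was passed over another column, and its RNA was sequenced. Samples were grouped as DMSO (2 libraries) and GSK (2 libraries) by the treatment label of the injected cancer cells.

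The authors deposited a table of normalised values on a log2 scale, with 22456 Ensembl mouse genes and 1 column per library. The submitters' processing notes name RSEM 1.2.29, Bowtie2 and DESeq2 1.12.4, and the builds mm10 and GRCh38, without roles. The transformation and the annotation release were not given in the sources used here. The log2 unit was taken from the values: they run from -1.035 to 20.58, with a median of 6.15 to 6.16 in each library. The values behave like a regularised logarithm, which pulls each gene towards its mean over the libraries, most where expression is low: the median range over 4 libraries was 0.113 for tested genes and 0.0178 for the 7908 genes below the filter. Differences on this scale understate the change of low genes, and read depth cannot be recovered from it. No sample column of the table was left unused. No gene had exactly equal values, at the full deposited precision, in both libraries of a group, and the median absolute difference between replicates was 0.0462 in DMSO and 0.0496 in GSK.

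Gene symbols and coordinates came from GENCODE M21 on GRCm38 (mm10), where 22335 identifiers matched. Tests ran in R 4.3.3 with limma 3.58.1, on the deposited log2 values with no pseudocount, for the 14548 genes with a mean of at least log2 of 10 (3.32). The linear model held the group only, the variance prior followed the mean (limma's trend), and p-values were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is limma's moderated standard error, SD the spread of the 2 libraries of a group, and fold changes are 2 to the power of the difference. No batch is given in the labels.

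Lists of fibroblast programmes and of markers of other cell types (36 lists), the tests and the rule for named genes were set before the data were examined. Lists with at least 5 tested genes (27) were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, each adjusted over the 27 lists. Members were counted over all genes tested and adjusted over the list alone. The rule named, per direction, the 10 largest changes among genes past the threshold with a mean of at least log2 of 50 (5.64) and non-overlapping groups, leaving out predicted genes and pseudogenes. It also named up to 4 members of each list with the smallest p, and always Acta2, Fap, Pdgfra, Pdgfrb, Pdpn, Col1a1, Tgfb1, Il6 and Cxcl12; some further genes that it named are not reported here. Col15a1, Ier2, Mmp9, Timp1, the MHC class II genes and Lcn2 as a cytokine gene were chosen after their values were seen.

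Transcripts of the named and called genes were aligned to all transcripts of the annotation with blastn 2.17.0, and matches of at least 98% identity over 200 bases to another gene were recorded. Of the 41 called genes, 4 are predicted genes or pseudogenes that share sequence with other genes: Gm6768 with Ncoa4, Gm18853 with Gm18852, Gm15459 with Hspa8 and Gm4294 with Rpl15. Their values are uncertain. So are those of Hspa1a and Hspa1b, of mt-Co3, and of Tgtp2, which matches Tgtp1.

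The gene test was tested on simulated data for the comparison of GSK with DMSO, on 14548 genes with the observed means and 2 libraries per group. Spreads were drawn from limma's own fitted variance prior with independent normal noise, so the simulation follows the model that the test assumes. Under that model the test called 21.6% of genes changed by 0.25 (log2), 92.1% of those changed by 0.5 and 99.2% of those changed by 1. Of its calls 4.96% were false, a share that this setting nearly fixes and that is no error rate for the real calls. Camera, run on independent simulated genes, called a list shifted by 0.3 in 20 of 20 runs and 2 of 500 unshifted lists. In the real data, the estimated correlation within the lists called at the preset correlation ran from -0.006 (universal fibroblast progenitor) to 0.785 (immediate early and dissociation stress). The simulation therefore does not give camera's share of false calls for correlated lists.

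Alternatives were other filters, quantile normalisation, scaling by the trimmed mean of M values (TMM, computed from its published formula), a variance prior without trend, the replicate number as a block, each library left out, an estimated correlation and fry. A threshold of 0.10, a robust variance prior and a correction for transcript length and GC content were added after seeing the data.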

Results

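RNA was sequenced from fibroblasts taken out of mouse mammary tumours. The tumours grew from 4T1 cells, a transplantable mammary carcinoma line of the Balb/c strain, and were collected 8 days after injection into the mammary fat pad. Before injection the 4T1 cells had been kept for 5 days in DMSO, the solvent, or in 5 µM of the compound GSK269962A. The fibroblasts are therefore host cells from tumours of pre-treated cancer cells; per the labels, it was the cancer cells that received the compound. The data hold 4 libraries, 2 from the DMSO group and 2 from the GSK group, and 22456 genes. Values are the authors' normalised expression on a log2 scale, between -1.035 and 20.58. Read counts were not given in the sources used here, so the depth of each library is unknown. The labels do not say whether the libraries of a group come from separate animals, so p-values measure only the spread between these samples.

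The 4 libraries carried a fibroblast profile. The 14 fibroblast identity genes averaged 14.06 and 14.00 (log2) in DMSO libraries 1 and 2 and 13.97 and 13.93 in GSK libraries 1 and 2, with Col1a1, the main chain of type I collagen, highest at 20.51. Pericyte and smooth muscle genes followed at 9.78, 9.96, 9.97 and 9.99. Genes of the cell types removed during isolation lay far lower: pan-leukocyte genes averaged 3.88 to 4.05 over the 4 libraries, endothelial genes 4.85 to 4.92 and epithelial or 4T1 genes 2.74 to 2.84. Single members stood above their lists, with Cd53 at 11.03, Flt1 at 10.84 and Krt19 at 8.82 the highest of these lists. In other leukocyte lists, Cd3e at 8.62, Csf1r at 8.28, Zbtb46 at 7.87 and Hdc at 7.06 also stood above the rest. Csf1r shares 873 bases with Hmgxb3 and is uncertain.

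**Figure D1:**
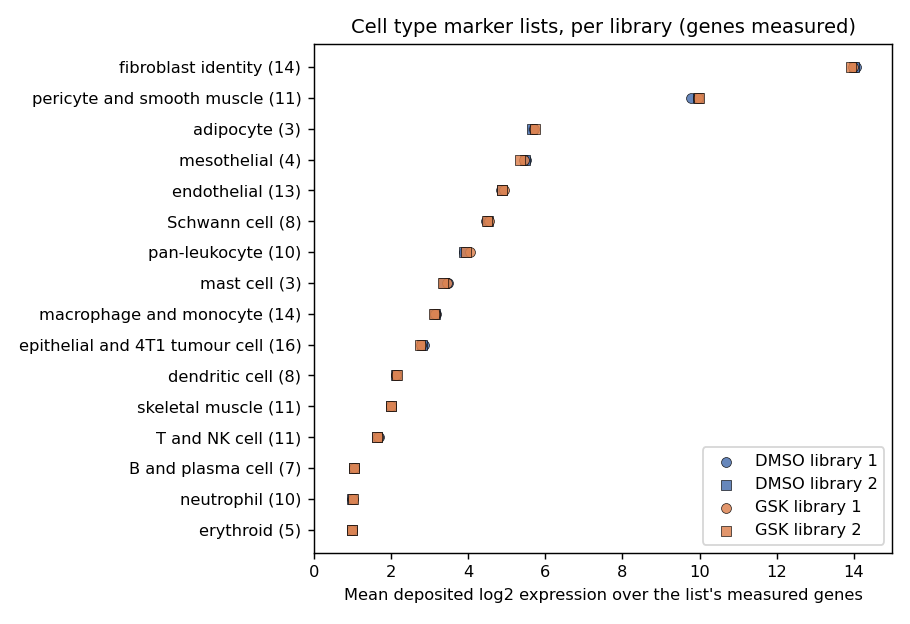
Mean deposited expression (log2) of each cell type marker list in each library, with circles and squares for libraries 1 and 2 of the DMSO (blue) and GSK (orange) groups and the number of measured genes in brackets. Fibroblast identity genes sit near 14 in all 4 libraries and leukocyte lists at or below 4.05.

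The comparison of GSK with DMSO asks how fibroblast activation differs when the cancer cells were pre-treated. Fibroblasts from GSK tumours expressed more of a pair of secreted matrix metalloproteinases, Mmp13, a collagenase, 3.57-fold higher, and Mmp10, a stromelysin, 2.53-fold higher. They expressed less of the cytokine gene Lif, 1.91-fold lower, of Tnfaip3, a feedback inhibitor of NF-kB signalling, 1.87-fold lower, and of Ptgs2, the inducible prostaglandin synthase, 1.79-fold lower. In limma, 41 of 14548 tested genes passed an adjusted p of 0.05, 22 higher and 19 lower in GSK, with changes between 0.26 in size and 1.83 (log2). Of the tested genes, 2330 had an unadjusted p under 0.05, where 727 would be expected with no change. In 7074 genes (48.6%) both GSK libraries lay on one side of both DMSO libraries, against 33.3% as the mean over all divisions into pairs. Genes vary together, so a division can exceed either expected number with no effect of the group, and neither excess is a test. The count depended on single libraries: 7 genes passed without DMSO library 1, 194 without DMSO library 2 and 70 without GSK library 1. It was 11 with a variance prior without trend, 23 after quantile normalisation and 138 with a robust prior. The deposited values appear shrunken towards each gene's mean, so fold changes are understated, most at low expression.

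Among the genes higher in GSK, Mmp13 (ENSMUSG00000050578, GRCm38 chromosome 9, 7272514 to 7283331) had 12.10 ± 0.33 (log2, mean ± SD) in DMSO and 13.94 ± 0.41 in GSK, a change of 1.83 ± 0.22 (SE) with a limma adjusted p of 0.046. Mmp10 (ENSMUSG00000047562, chromosome 9, 7502352 to 7510240) went from 10.39 ± 0.13 to 11.72 ± 0.29, a change of 1.34 ± 0.13 (adjusted p = 0.033). Kcnq3, a voltage-gated potassium channel subunit on chromosome 15 (65986387 to 66286642), rose by 0.95 ± 0.05 from 8.59 ± 0.07 to 9.54 ± 0.02 (adjusted p = 0.0085). Grem1, a secreted antagonist of bone morphogenetic proteins on chromosome 2 (113746164 to 113758646), rose by 0.90 ± 0.07 from 11.58 ± 0.13 to 12.48 ± 0.04 (adjusted p = 0.0199). The other genes named by the fixed rule rose by 0.56 to 0.82: Pla2g7, which degrades platelet-activating factor, by 0.82, Serpine2, a serine protease inhibitor, by 0.73, Wnt5a, a non-canonical Wnt ligand, by 0.67, Adgrl3, an adhesion receptor of the latrophilin family, by 0.57, and Prdm1, a transcriptional repressor, by 0.56. mt-Co3, a mitochondrial cytochrome oxidase subunit, was listed 1.56 ± 0.13 higher (adjusted p = 0.0251), but its 784 bases are identical over 783 to the nuclear pseudogene Gm28437, whose value was at -0.63, and both summed were 0.19 higher. The value of mt-Co3 is therefore uncertain. Without DMSO library 1, the genes of this paragraph past the threshold were Kcnq3, Grem1 and mt-Co3.

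Among the genes lower in GSK, Lif (ENSMUSG00000034394, chromosome 11, 4257557 to 4272514) went from 11.88 ± 0.01 in DMSO to 10.95 ± 0.14 in GSK, a change of -0.94 ± 0.07 (adjusted p = 0.0199). Tnfaip3 changed by -0.90 ± 0.10 (adjusted p = 0.0374), Ptgs2 by -0.84 ± 0.09 (adjusted p = 0.0364) and Il1rl1, an interleukin receptor on chromosome 1 (40429570 to 40465415), by -0.79 ± 0.05 (adjusted p = 0.00896). Dusp10, a phosphatase of stress-activated kinases, changed by -0.74. Angptl4, an inhibitor of lipoprotein lipase, changed by -0.70, Tnxb, the matrix glycoprotein tenascin X, by -0.65, Sbsn, suprabasin, by -0.64, and Hmox1, haem oxygenase, by -0.63. The inducible heat shock genes Hspa1b and Hspa1a changed by -0.72 and -0.61. Their transcripts match over 2201 bases at 99.23% identity, so reads could be divided between them, and summed they changed by -0.68, from 15.52 ± 0.07 to 14.85 ± 0.10. Of the 20 genes of the rule in both directions, 5 (Kcnq3, mt-Co3, Grem1, Il1rl1 and Dusp10) kept an adjusted p under 0.05 without DMSO library 1, and the 15 others, Mmp13, Mmp10 and Lif among them, lay between 0.0565 and 0.14. Without GSK library 1, Sbsn, Tnxb and Wnt5a missed the threshold (0.053 to 0.0543), and without GSK library 2, Hspa1b, Sbsn, Serpine2 and Tnxb did (0.0595 to 0.0727). With a variance prior without trend 13 of the 20 missed it (0.0516 to 0.0763), and after quantile normalisation 6 did (0.0523 to 0.0638). Mmp13, the largest change, missed it under 7 of 13 alternatives: without DMSO library 1 (0.0876), with no filter (0.0508), with a filter at a mean of 50 (0.0524), after quantile normalisation (0.0611), without trend (0.0763), with a robust prior (0.107) and with a length and GC correction (0.0506). Mmp10 missed it without DMSO library 1 (0.0737), without trend (0.0655) and with a robust prior (0.0631).

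**Figure D2:**
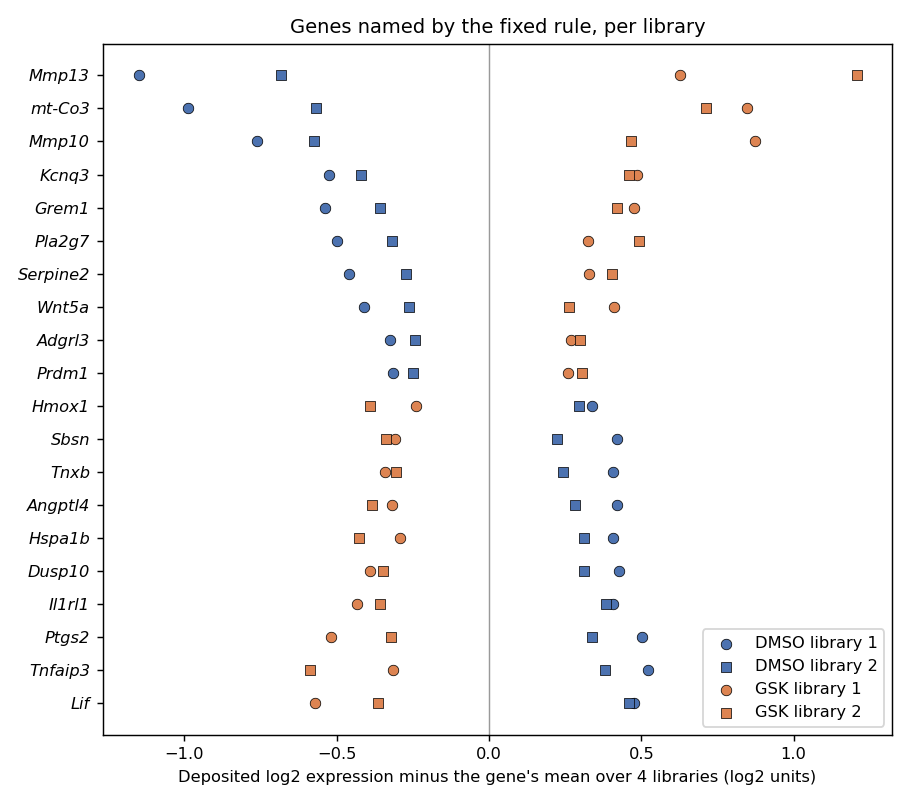
Expression of the 20 genes named by the fixed rule, as each library's deposited log2 value minus the gene's mean over the 4 libraries, with circles and squares for libraries 1 and 2 of the DMSO (blue) and GSK (orange) groups. For each gene both GSK libraries lie on one side of both DMSO libraries, with the widest separation for Mmp13 (change 1.83).

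Genes of fibroblast programmes were then compared as lists set before the data were examined. Camera with a preset correlation of 0.01 called 9 of 27 lists at an adjusted p under 0.05, 3 higher and 6 lower in GSK. With an estimated correlation none of the 27 was called (smallest adjusted p = 0.618, 1 list at an unadjusted p under 0.05), nor by the directional fry test (smallest adjusted p = 0.191, 2 lists at an unadjusted p under 0.05). With an estimated correlation, camera's p-value rests on the few residual degrees of freedom of 4 libraries, so hardly any list could pass. The universal fibroblast progenitor list lost its call at an estimated correlation of -0.006, below the preset 0.01. Its unadjusted camera p went from 1.2e-09 to 0.0229. A call missing under that test therefore does not show that correlation within the list undid it. Fry's test for change in either direction called 5 lists: antigen presentation, universal fibroblast progenitor, Wnt pathway, angiogenic and growth factors, and lipid and adipogenic.

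Inflammatory cytokine genes of cancer-associated fibroblasts were lower in GSK as a list by camera with the preset correlation only. Of 24 members, 2 fell over all genes tested, Lif and Ptgs2, and 15 fell when adjusted over the list alone, with none higher by either count. The median change was -0.55 (camera adjusted p = 2.51e-10, and adjusted p = 0.676 with an estimated correlation), and -0.331 without DMSO library 1. Ccl2, a monocyte chemoattractant, was at -0.78 ± 0.10 (adjusted p = 0.0543 over all genes), Has1, a hyaluronan synthase, at -0.56 ± 0.08 (adjusted p = 0.0556), and Il6 at -0.70 ± 0.15 (adjusted p = 0.114). Cxcl12 was at -0.21 ± 0.14 (adjusted p = 0.523), and at 0.01 without GSK library 2. Mean expression of each leukocyte list stayed at or below 4.05 in the libraries, though single members lay higher. Among epithelial and 4T1 markers, Krt19 and Lcn2 fell over their list alone, at -0.29 and -0.52, and that list was called lower without DMSO library 2 (camera adjusted p = 0.0236) and without GSK library 1 (0.0229).

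Immediate early and dissociation stress genes respond within minutes to hours to growth factors, stress or tissue digestion. They also were lower in GSK as a list by camera with the preset correlation only. All 20 members had a negative estimate, though that of Ier2 rounded to 0 and was 0.004 after quantile normalisation and 0.072 without DMSO library 1. Over all genes tested 2 fell, Hspa1a and Hspa1b, and 11 fell when adjusted over the list alone (median -0.25, camera adjusted p = 2.46e-12, and adjusted p = 0.676 with an estimated correlation). Myc was at -0.68 ± 0.09 (adjusted p = 0.0543) and Nr4a1, an orphan nuclear receptor, at -0.44 ± 0.06 (adjusted p = 0.0546).

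Universal fibroblast progenitor genes, which include markers of a Pi16-positive and of a Col15a1-positive state, made up the other list with a large shift. Of 15 members, Tnxb fell over all genes tested, and 12 fell and 1, Col15a1, rose when adjusted over the list alone. The median change was -0.41 (camera adjusted p = 8.1e-09, and adjusted p = 0.618 with an estimated correlation, where the unadjusted p was 0.0229). Pi16 was at -0.48 ± 0.07 (adjusted p = 0.0578), Dpt, dermatopontin, at -0.35 ± 0.05 (adjusted p = 0.0603) and Anxa3 at -0.29 ± 0.05 (adjusted p = 0.0703).

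Interferon response genes were higher in GSK as a list by camera with the preset correlation only. All 24 members had a positive change, none passed over all genes tested and 10 rose when adjusted over the list alone (median 0.18, camera adjusted p = 2.51e-10, and adjusted p = 0.676 with an estimated correlation). The median was 0.104 without DMSO library 1. Ifi44 was at 0.56 ± 0.09 (adjusted p = 0.0584), Bst2, which tethers budding virus, at 0.29 ± 0.04 (adjusted p = 0.0584) and Gbp3, a guanylate-binding protein, at 0.22 ± 0.04 (adjusted p = 0.0809). Of 13 antigen presentation genes none passed over all genes and 5 rose when adjusted over the list alone (median 0.13, camera adjusted p = 0.0083, and adjusted p = 0.676 with an estimated correlation). The examples belong to MHC class I, with B2m, its light chain, at 0.36 ± 0.06, the peptide-loading factor Tapbp at 0.28 ± 0.05, and the heavy chains H2-D1 at 0.29 ± 0.07 and H2-K1 at 0.19 ± 0.05. The MHC class II genes of the list, named after their values were seen, had negative estimates that did not pass by either count, with Cd74 at -0.15, H2-Ab1 at -0.10, H2-DMa at -0.06, H2-Eb1 at -0.04 and H2-Aa at -0.03. The antigen presentation call was lost without DMSO library 2 (camera adjusted p = 0.292) and without GSK library 1 (0.0573). The pan-leukocyte gene Cd53 was at 10.58 ± 0.17 in DMSO and 11.48 ± 0.46 in GSK (change 0.91 ± 0.20, adjusted p = 0.116), with a change of 0.577 without GSK library 1 and 1.234 without GSK library 2.

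Contractile myofibroblast genes were higher in GSK as a list by camera with the preset correlation only. None of 14 members passed over all genes, 1, Mylk, which encodes myosin light chain kinase, rose when adjusted over the list alone, and the median change was 0.20 (camera adjusted p = 9.02e-04, and adjusted p = 0.676 with an estimated correlation). Mylk was at 0.34 ± 0.07 (adjusted p = 0.0892), Lmod1 at 0.21 ± 0.07, Cald1 at 0.19 ± 0.07 and Tpm1 at 0.25 ± 0.09. Acta2, smooth muscle actin, was at 0.15 ± 0.11 (adjusted p = 0.552). Without DMSO library 1, Acta2 was at 0.005, Tpm1 at 0.136 and Lmod1 at 0.144. The list missed the threshold without DMSO library 1 (median 0.051, camera adjusted p = 0.14). Pericyte and smooth muscle markers, which share contractile genes, had a median change of 0.13 (camera adjusted p = 0.163) with none of 11 past the threshold by either count, and were called higher without DMSO library 2 (camera adjusted p = 0.00106). Cspg4 was at 0.49 ± 0.11 and Mcam at 0.34 ± 0.11, and at 0.31 and 0.157 without DMSO library 1. The pericyte and smooth muscle list averaged 9.78 in DMSO library 1 and 9.96 to 9.99 in the other libraries. The depletion did not target these cells, so a difference in their share cannot be told apart from a change in the fibroblasts.

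The 3 remaining lists that camera called lower had small medians. In the proliferation list none of 26 members passed by either count (median -0.09, camera adjusted p = 5.45e-05, and adjusted p = 0.676 with an estimated correlation), and Bub1b and Plk1, of mitosis, were at -0.16 and -0.15. Its median was -0.054 without GSK library 2 (camera adjusted p = 0.0326). In the hypoxia and glycolysis list none of 20 passed over all genes and 2 fell when adjusted over the list alone, Hk2, a hexokinase, at -0.39 ± 0.05 and Vegfa at -0.26 ± 0.05 (median -0.06, camera adjusted p = 0.0083, and adjusted p = 0.676 with an estimated correlation). This call was lost without DMSO library 1 (median -0.002, camera adjusted p = 0.247) and without GSK library 2 (median -0.031, 0.163), and the median was -0.139 without DMSO library 2 and -0.117 without GSK library 1. In the angiogenic and growth factor list, Angptl4 fell over all genes, and 4 of 23 members rose and 8 fell when adjusted over the list alone (median -0.06, camera adjusted p = 0.0369, and adjusted p = 0.676 with an estimated correlation). Vegfd, a lymphangiogenic factor, was at -0.42 ± 0.06, Gdf15 at -0.29 ± 0.04 and Fgf7 at -0.63 ± 0.11. That call was lost without GSK library 2 (camera adjusted p = 0.156) and with a variance prior without trend (0.0512).

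**Figure D3:**
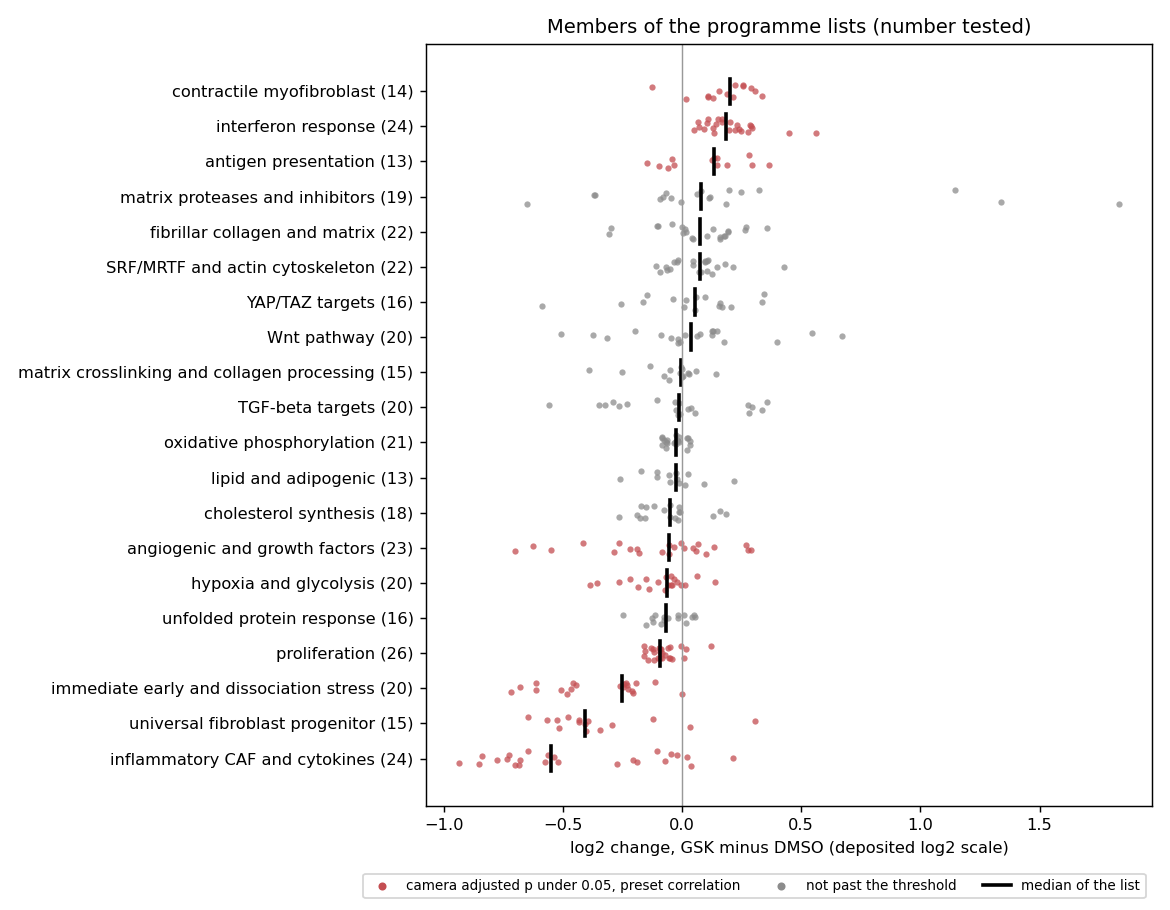
Change (log2, GSK minus DMSO) of each tested member of the 20 programme lists, with 1 point per gene, a black bar at the list's median and the number tested in brackets. Red points belong to the 9 lists past a camera adjusted p of 0.05 with a preset correlation, from cytokines (median -0.55) to contractile genes (median 0.20); no list passed with an estimated correlation.

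Among matrix protease genes single members rose while camera did not call the list in the model with the group only. Of 19 proteases and inhibitors, Mmp10 and Mmp13 rose over all genes, and 4 rose and 2 fell when adjusted over the list alone (median 0.08, camera adjusted p = 0.098). The others past the threshold over the list alone were Mmp9, Mmp11, Adamts1 and Timp1. Mmp9 was at 1.14 (limma adjusted p = 0.106 over all genes) and Mmp11 at 0.32 ± 0.07. Adamts1 was at -0.65 ± 0.08 (adjusted p = 0.0543) and Timp1 at -0.37 (adjusted p = 0.155). The list was called higher without GSK library 2 (camera adjusted p = 0.0213). Of 20 Wnt pathway genes, Wnt5a rose over all genes, and 3 rose and 3 fell over the list alone (median 0.04, camera adjusted p = 0.565). Dkk3 was at 0.55 ± 0.10, and the secreted Wnt modulators Sfrp4 and Sfrp1 were at -0.51 ± 0.07 and -0.32 ± 0.06. This list was called higher without GSK library 1 (camera adjusted p = 0.0253). None of 20 TGF-beta target genes passed over all genes, while 5 rose and 5 fell when adjusted over the list alone (median -0.01, camera adjusted p = 0.491). Inhba was at 0.28, and Bhlhe40, Smad7 and Tgfbi were at -0.32, -0.26 and -0.35. Tgfb1 itself was at 0.29 ± 0.07 (adjusted p = 0.12).

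Matrix structure and cytoskeletal lists were not called by camera on the deposited values of all 4 libraries, in the model with the group only. None of 22 fibrillar collagen and matrix genes passed by either count (median 0.08, camera adjusted p = 0.163). Col1a1 was at 20.50 ± 0.03 in DMSO and 20.52 ± 0.08 in GSK, a change of 0.02 with a 95% interval from -0.57 to 0.60, and this interval leaves room for sizeable changes. The interval follows limma's moderated SE of 0.24, which the variance prior at this high expression widens well beyond the spread of these libraries. The sign of the Col1a1 change turned without DMSO library 1 (-0.003) and without GSK library 2 (-0.043). None of 15 crosslinking and collagen processing genes passed by either count (median -0.01, camera adjusted p = 0.491). Of 16 YAP/TAZ target genes none passed over all genes and 2 fell over the list alone (median 0.05, camera adjusted p = 0.491). F3, tissue factor, was at -0.59 and Ankrd1 at -0.26. Of 22 SRF/MRTF and actin cytoskeleton genes none passed over all genes and 1, Myh10, a non-muscle myosin heavy chain, rose over the list alone (median 0.07, camera adjusted p = 0.114); the list was called higher after quantile normalisation (camera adjusted p = 0.0077) and without DMSO library 2 (0.0224).

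Metabolic and housekeeping lists were not called by camera in that model either, and none of their members passed over all genes tested. The unfolded protein response list (16 genes) had a median of -0.07 (camera adjusted p = 0.114) and was called lower without GSK library 1 (0.00102). Oxidative phosphorylation (21 nuclear genes) had a median of -0.02 (camera adjusted p = 0.142). Cholesterol synthesis (18 genes) had a median of -0.05 (camera adjusted p = 0.103) and was called lower without DMSO library 1 (9.24e-04) and without GSK library 2 (5.84e-05). In these 3 lists no member passed when adjusted over the list alone. In the lipid and adipogenic list (13 genes, median -0.03, camera adjusted p = 0.163), 1 gene fell over the list alone, Dgat2, which makes triglycerides, at -0.26.

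Lists of markers of fibroblasts and of other cell types were not called by camera in the model with the group only, and no marker gene passed over all genes tested. In the fibroblast identity list (14 genes, median -0.02, camera adjusted p = 0.256) Pdgfrb rose and S100a4 fell when adjusted over the list alone, at 0.33 ± 0.08 and -0.67 ± 0.11. S100a4 shares 302 bases with Gm42674 and is uncertain. Pdgfra was at -0.04 ± 0.06 and turned to 0.007 without GSK library 2, Fap was at 0.12 ± 0.08 (0.013 without GSK library 2) and Pdpn at -0.37 ± 0.11 (-0.236 without DMSO library 1). In the epithelial and 4T1 list (7 genes, median -0.04, camera adjusted p = 0.114) Krt19 and Lcn2 fell over the list alone, at -0.29 (-0.177 without GSK library 2) and -0.52 (-0.286 without DMSO library 1); Lcn2 is also a cytokine list member. This list was called lower without DMSO library 2 (camera adjusted p = 0.0236) and without GSK library 1 (0.0229). The pan-leukocyte list (5 genes, median 0.06, camera adjusted p = 0.114) had Cd53 higher over the list alone and was called higher without GSK library 2 (camera adjusted p = 0.00135). Endothelial (8 genes, median 0.02), macrophage and monocyte (5 genes, median -0.03) and Schwann cell genes (6 genes, median -0.0025, where camera's direction was up) had camera adjusted p of 0.491, 0.256 and 0.904, with no member past the threshold by either count. The lists of neutrophil (2 genes), T and NK cell (2), B and plasma cell (1), dendritic cell (1), mast cell (2), adipocyte (2), skeletal muscle (3), mesothelial (2) and erythroid genes (0) had too few tested genes for a list test. Among them Krt19, in the mesothelial list, fell over the list alone.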

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

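The threshold of 0.10, the robust prior and the length and GC correction were chosen after seeing the data; the other alternatives were planned. Of the 41 genes called, 33 passed with no filter, 34 with a filter at a mean of 50, 41 with TMM scaling and 38 with the length and GC correction, where 33, 34, 42 and 47 genes passed in all. Quantile normalisation gave 23 (11 higher, 12 lower), with 22 of the 41 among them. The prior without trend gave 11 (5 higher, 6 lower), all 11 from the 41. The robust prior gave 138 (63 higher, 75 lower), with 39 of the 41 among them, and a threshold of 0.10 gave 363 (170 higher, 193 lower). The cause was not tested beyond the looser threshold itself. All 41 kept their direction under every alternative, except that 39 were tested with the filter at 50. This was largely fixed in advance. The groups of each called gene do not overlap, so no single library left out can turn its direction. Filters, variance priors, the looser threshold and the replicate block leave the estimated change as it is. Leaving out single libraries gave 7 to 194 genes, 4 to 72 higher and 3 to 122 lower, with 8 to 11 lists and 0 to 2 marker lists called; such fits leave a group with 1 library, assumed to vary like the other group. Without DMSO library 2, 37.1% of calls were higher, against 53.7% with all libraries. With an estimated correlation 0 lists were called, and by fry 0. At an unadjusted p under 0.05 there were 1 and 2. The universal fibroblast progenitor (-0.006) and angiogenic and growth factor lists (0.003) lost their calls with estimates below the preset 0.01. Their unadjusted camera p went from 1.2e-09 to 0.0229 and from 0.0123 to 0.116. For them correlation was not the cause, and the few residual degrees of freedom of 4 libraries limit that test. The cause for fry was not tested. Mmp13 had an adjusted p of 3.75e-06 to 0.107 over the alternatives. With single libraries left out, values ran from -0.091 to 0.007 for Pdgfra, -0.043 to 0.076 for Col1a1, -0.429 to 0.013 for Cxcl12 and -0.072 to 0.072 for Ier2, none of them called. Their signs turned without DMSO library 1 for Col1a1 (-0.003) and Ier2 (0.072), and without GSK library 2 for Pdgfra (0.007), Col1a1 (-0.043), Cxcl12 (0.013) and Ier2 (0.035); that of Ier2 also turned after quantile normalisation (0.004). At the preset correlation, the 9 called lists kept their direction under each alternative that gave camera results, and their call in 92 results against 7 that missed the threshold. Several of these alternatives reuse the same changes, and none of the 9 lists kept its call with an estimated correlation or by directional fry. Among named genes, 1689 results kept direction and side of the threshold, 174 newly passed and 72 no longer passed. Of the 174, 83 came with the replicate block, whose pairing the labels do not give, and 40 with the threshold of 0.10 alone.

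Replicate numbers 1 and 2 occur in both groups, but the labels do not say that they pair samples, and 2 pairs cannot show it. With the number as a block, 1374 genes passed (661 higher, 713 lower), all 41 among them, and 12 lists, with the protease (camera adjusted p = 0.0416), SRF/MRTF (0.0373) and cholesterol lists (0.0416) added. The differences between replicates 1 and 2 correlated between the groups across genes (r = 0.428, rho = 0.355; genes are not independent replicates). Other pseudocounts were not run, since the values are logarithms, nor a count test, since no whole reads can be recovered. Without depth, changes of low genes cannot be resolved.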

Other observations

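The tests of technical explanations, the divisions of the libraries, and the genes outside the fixed rule and lists were chosen after the results were seen. Of the genes of the circadian clock, Nr1d1, a repressor of the loop, fell by 0.57 (SE 0.04, limma adjusted p = 0.0199; 269 bases overlap Thra). Per1 was at -0.47 ± 0.07 (adjusted p = 0.0576), Cry2 at -0.27, Nfil3 at -0.31 and Nr1d2 at -0.21, while Arntl was at 0.05 and Dbp at -0.13, and none of these passed the threshold. Dusp6, a feedback phosphatase of ERK signalling, rose by 0.41 ± 0.05 (adjusted p = 0.0382), and Spry4 and Etv4 were at 0.24 ± 0.04 and 0.44 ± 0.08, but Spry2 was at -0.29 ± 0.06. Further NF-kB-responsive genes beside Tnfaip3 were at -0.68 ± 0.12 (Nfkbia), -0.80 ± 0.17 (Tnfaip6) and -0.73 ± 0.10 (Ptx3), with adjusted p of 0.0703, 0.108 and 0.0546. The glucocorticoid-responsive kinase gene Sgk1 fell by 0.61 (adjusted p = 0.0366) and Tmem119 rose by 0.49 ± 0.05 (adjusted p = 0.0366). Without DMSO library 1 the adjusted p was 0.0685 for Nr1d1, 0.146 for Dusp6, 0.0756 for Sgk1 and 0.149 for Tmem119. Without GSK library 2 it was 0.0819 for Dusp6, 0.0595 for Sgk1 and 0.0759 for Tmem119, and without GSK library 1 it was 0.0543 for Sgk1. Among matrix and tumour fibroblast genes, Col7a1, the anchoring fibril collagen, was at 0.73 ± 0.10 (adjusted p = 0.0543), Lrrc15, a marker of matrix-producing tumour fibroblasts, at 0.44 ± 0.13 (0.191) and Spp1 at 0.36 ± 0.13 (0.242).

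Mmp13 and Mmp10 lie in the metalloproteinase gene cluster of chromosome 9, where no other tested member passed the threshold: Mmp12 was at 0.45 ± 0.07 (adjusted p = 0.0584), Mmp3 at 0.11 ± 0.05, Mmp8 at 0.10 ± 0.05 and Mmp27 at -0.12 ± 0.08. Mmp3, which lies between Mmp13 and Mmp10, was expressed at 12.78 ± 0.02 in DMSO and 12.89 ± 0.01 in GSK. The Hox genes Hoxc10, Hoxa9 and Hoxa10 had wide spreads in the GSK group: Hoxc10 averaged 9.17 ± 0.08 in DMSO and 8.34 ± 1.03 in GSK, Hoxa9 7.20 ± 0.10 and 6.79 ± 0.50, and Hoxa10 6.84 ± 0.17 and 6.50 ± 0.41, with none past the threshold and changes of -0.104, -0.061 and -0.053 without GSK library 1. Cd3e, a T cell receptor chain, was listed at 8.62, while the median gene of the T and NK cell list was at 0.015.

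Cytokine and immediate early transcripts were lower in GSK as lists by camera with a preset correlation only: over all genes 2 of 24 and 2 of 20 members passed, and with an estimated correlation neither list did (adjusted p = 0.676 for each). Leukocytes carried over into the DMSO libraries would bring their own abundant transcripts, yet the 33 measured pan-leukocyte, macrophage and neutrophil markers without Cd53 summed to 642.8 (back-transformed) in DMSO, 2.18% of the fall of 29490 summed over 15 cytokine genes (1.79% to 2.82% over library pairs). With T and NK, B and plasma, dendritic and mast cell markers added, 62 genes summed to 1636, 5.55% of the fall (4.72% to 6.91%). Tumour cell markers were also low in the DMSO libraries beside the cytokine fall: 15 epithelial and 4T1 markers without Lcn2 summed to 622.5, 2.11% of it (1.73% to 2.74%), with Krt19 at 499, Krt18 at 21.2 and Krt8 at 12.3. The 15 cytokine genes were those that fell over their list alone in these same libraries. How much cytokine RNA leukocytes or tumour cells hold per marker transcript is not known here, so these sums cannot exclude either source. A contribution of tumour cells stays open, since Krt19 was at -0.29. A difference in handling stress between the preparations cannot be told apart from an effect of the pre-treated cancer cells on the fibroblasts. The dissociation stress list had a median change of -0.254 (-0.123 to -0.449 over library pairs), with heat shock genes at -0.562 and the earliest genes, such as Fos and Jun, at -0.211. Between replicates (library 1 minus 2) the list's median difference was 0.123 in DMSO and 0.196 in GSK. The smallest group difference thus lay within the replicate spread. The genes of this list are also part of the pattern itself, and no other value here separates both explanations.

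mt-Co3 was higher by 1.56 in GSK, beyond other mitochondrial genes. More mitochondrial RNA in GSK cannot be the whole account, since the 6 protein genes with no near-identical nuclear copy had a median change of 0.236 (0.12 to 0.368). Reads divided differently between mt-Co3 and Gm28437 are a candidate explanation: summed, the pair changed by 0.188, within that range. mt-Co2, with the copy Gm28661, moved from 1.10 alone to 0.19 summed, and mt-Atp6, with the copy Gm10925, from -0.69 to 0.16. The smaller rise of the mitochondrial genes stays open.

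Cd53, a leukocyte tetraspanin, was at 1532 (back-transformed) in DMSO and 2935 in GSK, short of the threshold (adjusted p = 0.116), with a change of 0.577 without GSK library 1 and 1.234 without GSK library 2. Leukocytes carried over into the GSK libraries would bring the other pan-leukocyte genes too, but the 9 others measured summed to 101 in GSK, 7.18% of the rise of Cd53 (at most 16% over library pairs), after a depletion for CD45. Whether the fibroblasts express Cd53, and differently with the pre-treatment, was not tested and stays open.

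The 4 libraries can be divided into pairs in 3 ways, too few for a share under 0.05. The real division gave 41 genes and the highest of the others 0 (limma, with 566 and 75 genes at an unadjusted p under 0.05 in the others, against 2330). In the other divisions a DMSO and a GSK library share each group. Any difference between GSK and DMSO then adds to the spread within groups and lowers the calls. Both counts lay below the 727 expected with no change, so the 0 is no fair comparison for the 41. The number of divisions with as many calls, the real one included, was 1.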
